A study of Mus with 4 samples.

How the data were processed

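Total RNA (100 ng) of tumor tissue from mice that were 4 to 6 weeks old when bought was labelled with biotin and hybridized to Affymetrix arrays, per the labels' protocols. The series has 4 arrays in 4 groups, shCtrl-NC, shNrf3-NC, shCtrl-HFD and shNrf3-HFD, with 1 array in each. The deposited values are on the log2 scale and were made by the authors with Affymetrix Expression Console and its RMA method, per the submitters' processing notes, whose versions are not given in the sources used here. The table holds 28846 rows, of which 22206 are transcript rows and 6640 are control rows, and its values run from 1.50 to a shared highest value of 19.93. At that highest value 5 genes lay on at least 1 array and 3 on all 4. Medians over all rows were 5.81, 5.73, 5.74 and 5.77 in the group order above, and SDs 3.02, 3.17, 3.21 and 3.11. An array gives no depth of counts. Its signal over background is bounded by the negative control rows, whose medians were 5.35 to 5.39 and whose 95th percentiles were 9.35, 9.00, 8.97 and 9.13.

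Probe sets were named from the platform annotation given with the data. It gave 1 gene symbol for 19572 probe sets and several for 0, and 2634 transcript rows are unnamed here. All 19572 Entrez IDs matched a RefSeq gene table of mouse assembly GRCm38.p6, used only for names. Of 19505 genes 55 had several probe sets, and the probe set with the highest mean was taken. Genes were filtered at a mean of 5.73 or more, the median over all rows, which left 10021. That filter lies far below the 95th percentile of the negative control rows, so a stricter one at the 75th percentile (8.45) was an alternative. No coordinates are given, since the build behind the array's annotation is not given in the sources used here.

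The comparisons were shNrf3 minus shCtrl in each diet and HFD minus NC for each construct, the genes shared by both of a kind, and the knockdown difference in HFD minus that in NC. With 1 array per group there is no test of a single comparison, and genes at a difference of 1 or more on the log2 scale (2-fold) are counted. Counts shared by 2 comparisons stand beside the number that independent lists of the same sizes would share. Comparisons with an array in common were not correlated. An additive model of construct and diet was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, Benjamini-Hochberg adjustment). Its 1 residual degree of freedom per gene is the construct by diet interaction, which is taken for the error. On simulated values of 10021 genes with 50 changed by construct at each of 4 sizes, this fit recovered 10% of those changed by 1 on the log2 scale, 80% of those changed by 2 and 100% of those changed by 3 or 4, and called 8 of 9821 unchanged genes. The noise of that simulation was of 1 size for every gene, and it held no diet differences and no shift between arrays. These shares therefore need not hold for the deposited values.

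For each of 33 gene lists (18 of pathways and 15 of cell types, 714 of 809 entries measured) the median difference of the measured members is given, with its percentile among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. Members 1.5-fold or more higher or lower were counted. The pathway lists were proteasome, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, NRF2-type antioxidant genes, ATF4 and amino acid response, endocytosis and macropinocytosis, cell cycle, p53 and apoptosis, hypoxia and glycolysis, unfolded protein and heat shock, immediate early genes, type I interferon, interferon-gamma and antigen presentation, inflammatory cytokines and chemokines, extracellular matrix, oxidative phosphorylation and ribosomal proteins. The cell type lists covered epithelium and renal tubule, T cells, cytotoxic lymphocytes, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells and eosinophils, fibroblasts and pericytes, endothelium, adipocytes, skeletal muscle, keratinocytes and skin, erythroid cells and platelets, and nerve and Schwann cells.

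Genes were named by a rule fixed, with the lists, the fits and most alternatives, before the data were examined. It takes Nfe2l3, the 10 genes higher and the 10 lower with the largest smaller-of-both difference for knockdown and for diet (the same sign and at least 1.5-fold in both), the 5 largest each way in each single comparison and in the construct by diet difference, and 2 to 4 members of each list described with the largest absolute averaged difference for that comparison, with members past the threshold of the additive fit. For the construct by diet comparison, where the fixed rule names no averaged difference, list members were ranked by the construct by diet difference, a choice made after the values were seen, as was naming Des and Cyp2f2. Predicted genes, clone names, olfactory and vomeronasal receptors and immune receptor segments were counted but not named.

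Alternatives were no filter, the filter at the 75th percentile, the filter on the highest of the 4 arrays, cyclic loess between arrays (limma), centring of each array on its median over the filtered genes, the mean of all probe sets of a gene, a threshold of 1.5-fold, eBayes with trend and robust settings, list means, and list members past the filter only. Nfe2l3 has 1 probe set, so the mean over probe sets changes nothing for it. Leaving out each array in turn for the shared counts was added after the data were seen, as were setting readings below the median of the negative control rows of their array to that median, and the additive fits with the filter on the highest array, centred arrays and the mean of probe sets. A single gene's value is called moved when it changed by more than 0.47, the SD over genes of the averaged contrast that belongs to neither factor, a list median when it changed by more than the range of its random lists allows to either side, a correlation when it changed by more than 0.05, and a count when it changed by more than 1.5 times. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.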

Results

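RNA of subcutaneous tumors was measured on 4 Affymetrix arrays, 1 for each of 4 groups. The tumors grew from Renca cells, a mouse renal adenocarcinoma line, that carried a short hairpin RNA against Nrf3 (shNrf3) or a control hairpin (shCtrl). Nrf3 is the transcription factor encoded by Nfe2l3, of the cap'n'collar family to which NRF2 belongs. The cells were injected into the flanks of male BALB/c mice that had eaten normal chow (NC) or a high-fat diet (HFD) for 17 weeks, and the tumors were removed 2 weeks later. The design asks how knockdown of Nrf3 in the tumor cells, the diet of the host and the combination of both bear on expression in the tumor. Each group has 1 array, and the labels do not say whether an array holds RNA of 1 tumor or of several. No difference between 2 arrays below therefore has a replicate check, and the number of arrays limits the precision. Values are on the log2 scale, and a difference of 1 is 2-fold. Levels near 5.4 lie at the median of the negative control rows (5.35 to 5.39 on the 4 arrays), so differences are given on the log2 scale, and a fold only where both arrays lie well above it. Where 1 of 2 arrays read below its own control median, that reading was set to the median, and the difference is a bound, written "or more" or "or lower".

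The targeted gene did not follow the labels in both diets. Nfe2l3, represented by 1 probe set, read 6.22 on the array labelled shCtrl-NC and 5.56 on that labelled shNrf3-NC, a difference of -0.66. It read 5.77 on the array labelled shCtrl-HFD and 6.05 on that labelled shNrf3-HFD, a difference of 0.28, which goes against the label. Both differences lay within the middle 95% of those of the 1000 genes nearest in level, at the 18.3rd percentile in NC and the 66.4th in HFD. On all 4 arrays the probe set read far below the 95th percentile of the negative control rows (8.97 to 9.35). The NC difference has the sign of the labels but lies within the scatter at this level, so Nfe2l3 bears out the labels of neither diet. Groups are therefore called by the label of their array, and every direction given below in either diet rests on these labels. A knockdown difference is named by the labels and not by a measured loss of Nfe2l3.

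Interferon-gamma and antigen presentation genes were higher in the tumors labelled shNrf3 in both diets. In NC 25 of the 28 measured members were 1.5-fold or more higher and 0 lower, with a median difference of 1.66. In HFD 13 were higher and 1 lower, with a median of 0.49. The members Psmb9, Psmb10 and Cxcl11 were higher in NC but differed little in HFD (values under the other observations). Both medians lay above those of nearly all of 10000 random lists matched on level (percentile 100.0 in each). Medians outside the middle 95% of random lists were common, however. For knockdown 14 of the 33 lists lay above that range and 4 below it in NC, and 5 and 8 in HFD. For diet 10 lay above and 5 below with shCtrl, and 1 and 16 with shNrf3. A percentile outside that range therefore does not by itself set a list apart from the others. Cxcl9, a chemokine that draws T cells, was 19.0-fold higher in NC (difference 4.25) and 9.43-fold higher in HFD (3.24), first in rank among the genes higher in both diets. The MHC class II genes H2-Ab1 (4.21 in NC and 2.03 in HFD), H2-Aa (3.84 and 1.68) and H2-Eb1 (3.40 and 1.65) and H2-DMb2 (3.96 and 2.22), which helps load peptides on class II molecules, went the same way. Genes of the H2 family are close in sequence, so the probe sets of single members are uncertain. In NC skeletal muscle and adipocyte markers were also higher on the array labelled shNrf3, as given below. Whether the NC differences of immune genes have the same source was not tested.

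Markers of macrophages and monocytes were also higher. Of 27 measured markers 22 were higher in NC and 12 in HFD, against 1 and 2 lower, with medians of 1.38 and 0.43 (percentile 100.0 in each). Among them were the arginase gene Arg1 (1.51 and 2.65) and Folr2 (2.76 and 0.94) and Ly6c1 (2.45 and 1.31), whose near-identical copy Ly6c2 makes its probe set uncertain. Neutrophil markers had medians of 0.89 and 0.20 (percentiles 100.0 and 99.0, with 0.31 in HFD after cyclic loess and a mean of 0.10). Of 20 measured, 12 were higher and 2 lower in NC, and 5 were higher and 5 lower in HFD. Acod1, which makes itaconate, had the largest difference (2.89 and 1.92), while the gelatinase gene Mmp9 was lower in both diets (-1.78 in NC). Cytotoxic lymphocyte genes had medians of 0.69 and 0.48 (percentiles 100.0 and 99.7, with 1.505 and 0.79 over members past the filter on level only and a mean of 1.12 in NC), with granzyme B (Gzmb) at 4.20 and 1.67 and Klrd1 at 1.71 or more and 0.45 or more. The Gzm genes lie in a cluster of similar copies. Inflammatory cytokine and chemokine genes had medians of 0.89 and 0.28 (percentile 100.0 in each, with 0.50 in HFD after centring each array on its median). Tslp (2.51 and 1.25), Lcn2 (1.88 and 0.96) and Ccl2 (1.19 and 1.57) were higher in both diets and Ccl5 in NC (3.08 or more, and -0.01 in HFD). T cell markers had a median of 0.42 in NC (percentile 99.6, with 0.21 after centring) and of -0.06 in HFD (percentile 30.4). Further genes higher in both diets were Mid1, a microtubule-associated ubiquitin ligase (2.68 and 3.74), the complement gene C6 (3.04 and 2.61), Clec12a (3.16 and 1.69) and the peptide and histidine transporter Slc15a3 (3.30 and 1.67).

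Matrix genes were lower in the tumors labelled shNrf3 in both diets. Of 27 extracellular matrix and remodelling genes 12 were 1.5-fold or more lower in NC and 21 in HFD, against 2 and 1 higher, with medians of -0.34 and -1.17 (percentiles 0.01 and 0.00). After loess the NC median was -0.66, with 17 lower, and the HFD median -1.03, with 18 lower. The mean of the members in NC was -0.56. In HFD adipocyte markers were lower too (12 of 20, median -1.02, percentile 0.00). Lumican (Lum) differed by -1.96 in NC and -3.03 in HFD, the stromelysin gene Mmp10 by -1.88 and -2.37, periostin (Postn) by -2.13 and -1.41 and Col6a2 by -1.40 and -1.79. The fibroblast and pericyte list, which shares 3 collagen genes, lumican and decorin with the matrix list, had medians of -0.40 and -0.92 (percentiles 0.20 and 0.00, with -0.60 in NC after centring and a mean of -0.09 there), with the PDGF receptor gene Pdgfrb at -1.40 and -1.92. Endothelial markers had medians of -0.36 and -0.33, with 9 of 19 lower and 3 higher in NC and 5 lower and 0 higher in HFD. The HFD median lay within the middle 95% of random lists (percentiles 2.26 and 3.62), and after cyclic loess between arrays the NC median did (4.13 and 1.64). After centring the NC median was -0.57. Among these markers VE-cadherin (Cdh5) differed by -1.97 and -1.61, and the VEGF receptor genes Kdr and Flt1 by -1.56 and -1.57 and by -1.25 and -1.87. Lyve1, a lymphatic vessel gene that some macrophages also express, differed by 2.46 in NC and -0.46 in HFD. The transcriptional repressor gene Prdm1 was lower in both diets (-2.83 and -3.29), as were the desmosomal cadherin gene Dsc2 (-2.14 or lower and -2.74 or lower), Crabp1 (-2.20 and -3.97), Arhgap32 (-2.16 and -2.29), Tnfrsf22 (-2.27 and -1.75) and C1qtnf3 (-1.71, and -2.91 or lower).

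Keratinocyte and skin genes were also lower in the tumors labelled shNrf3, with medians of -0.66 in NC and -0.73 in HFD (percentiles 0.05 and 0.00). The members Dsc3, Krt5, Krt10, Dsg1a, Krt77, Trp63 and Sprr1a read below the control median on some or all arrays, which limits these medians. Dsc3 differed by -0.51 or lower and -1.07 or lower. Krt10, a keratin of differentiated epidermis, differed by -1.10 or lower and -4.12 or lower and read 9.50 on the shCtrl-HFD array alone, against 4.72 to 6.45 on the other 3. Epithelial and renal tubule genes had medians of -0.19 and -0.45 (percentiles 9.61 and 1.33, with -0.24 in HFD after centring, -0.69 over members past the filter only and a mean of -0.29).

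**Figure D1:**
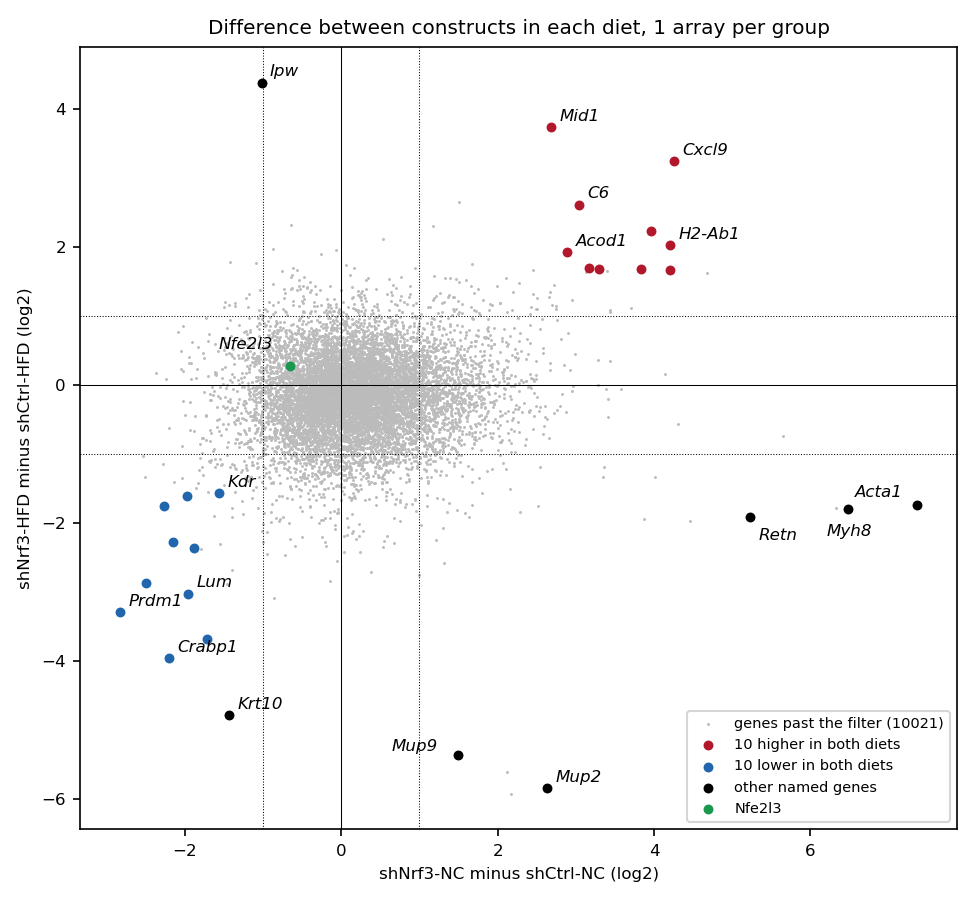
Each point is a gene past the filter on level, plotted by its shNrf3 minus shCtrl difference (log2) in NC on the x axis and in HFD on the y axis, with dotted lines at 2-fold. Cxcl9 and H2-Ab1 lie high and Prdm1 and Lum low in both diets, while Acta1 and Retn stand high in NC and Mup2 low in HFD, and Nfe2l3 (green) lies among the bulk of the genes at -0.66 and 0.28.

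Over the 10021 genes past a filter on level, 84 were 2-fold or more higher in both diets, where 2 independent lists of these sizes would share 34.1, and 83 were lower in both, where 32.3 would be shared. In opposite ways, 81 were higher in NC and lower in HFD (95 for independent lists) and 15 the reverse (11.6). After cyclic loess these opposite counts were 48 (54.8) and 24 (20.9). Across genes the knockdown differences in the 2 diets, which have no array in common, correlated with Pearson's r of 0.09 and Spearman's rho of 0.07. Genes are not independent replicates, and r was -0.03 with no filter on level and 0.19 with a stricter one. After cyclic loess between arrays 80 of the 84 and 65 of the 83 were again 2-fold or more the same way in both diets. With 1 array left out, where a gene has to pass 2 comparisons that share an array, the counts were 101 to 697 higher (highest without shCtrl-HFD) and 119 to 240 lower (highest without shCtrl-NC).

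In an additive limma fit of construct and diet, whose 1 residual degree of freedom is the construct by diet interaction, 0 genes passed an adjusted p of 0.05 for the construct. Of 10021 genes 447 had an unadjusted p under 0.05 in this limma fit, a smaller share than the 0.05 expected with no differences. In the limma fits with loess and centred values 676 of 10031 and 689 of 10021 did, a larger share. The smallest adjusted p was 0.52, shared by Cxcl9 (log2 difference 3.74 ± 0.43, SE). How many genes it called depended on the scaling. With cyclic loess values the same fit called 9 genes. Cxcl9, C6, Mid1, H2-DMb2 and H2-Ab1 were higher and Prdm1, Crabp1, Dsc2 and Lum lower, with adjusted p from 0.0104 to 0.0493. After centring each array on its median, a limma fit added after the data were seen, 17 genes were called higher and 10 lower, these 9 among them, with adjusted p from 0.000710 (Cxcl9) to 0.0478. Over the 10 limma fits run the smallest adjusted p ran from 0.000710 to 0.869. The fit takes the interaction as its error and holds nothing of the spread between tumors of 1 group.

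Counts of genes in single comparisons depended on the scaling. In NC 1334 genes were 2-fold or more higher and 453 lower in the array labelled shNrf3, so that 74.7% of them were higher, with a median difference of 0.14 over all filtered genes. After cyclic loess 63.0% were higher (1056 against 619), and after centring each array on its median 53.9% (922 against 790). In HFD 256 were higher and 714 lower (26.4% higher, median difference -0.14), against 339 and 521 after loess (39.4%) and 481 and 383 after centring (55.7%). Counted from its own median difference, each comparison had 1047 higher and 661 lower in NC and 386 and 469 in HFD.

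In NC, muscle and fat genes were higher in the array labelled shNrf3. The 5 genes with the largest difference in NC were skeletal muscle actin (Acta1, 12.51 on the shNrf3-NC array against 4.73 to 6.48 on the other 3), the myosin genes Myl1 (6.00 or more), Myh8 (5.40 or more) and Myh4 (4.83 or more) and the adipokine gene Retn (5.23). Except for Retn they read below the control median on the shCtrl-NC array, so their order is not read. Skeletal muscle markers had a median of 1.12 in NC, with 20 of 32 higher (percentile 100.0, with 1.98 over members past the filter only), and of 0.02 in HFD (percentile 43.8). Adipocyte markers had a median of 1.03 in NC (13 of 20 higher, percentile 100.0) and of -1.02 in HFD (12 lower, percentile 0.00), with adiponectin (Adipoq) at 3.35 and -1.33. Desmin (Des), listed with pericytes and also a muscle gene, differed by 3.31 or more in NC and read below the control median on both HFD arrays. Fatty acid synthesis genes, 1 of which is also among the adipocyte markers, had medians of 1.02 and -0.47 (percentiles 100.0 and 2.51). Of 15 measured, 9 were 1.5-fold or more higher and 0 lower in NC, and 2 were higher and 6 lower in HFD. Largest in averaged difference were the stearoyl-CoA desaturase gene Scd1 (3.41 and -0.47), Elovl5 (1.47 and 0.34) and Fads1 (1.48 and 0.23). Elovl5 and Fads1 thus went against the HFD median. Largest in the other direction in NC, beside Prdm1, were Moxd1 (-2.53) and Safb (-2.37). Dsc2 and Fgfbp1 (-1.51 or lower) ranked with them only through readings below the control median. In HFD the non-coding RNA Ipw read 9.23 on the array labelled shNrf3-HFD and 3.92 to 4.94, below the control median, on the other 3. The 4 lowest genes of that comparison were the major urinary protein genes Mup22, Mup2, Mup19 and Mup9, with differences from -5.93 to -5.36. Mup genes are nearly identical to one another, and the probe sets cannot be taken to read single members.

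**Figure D2:**
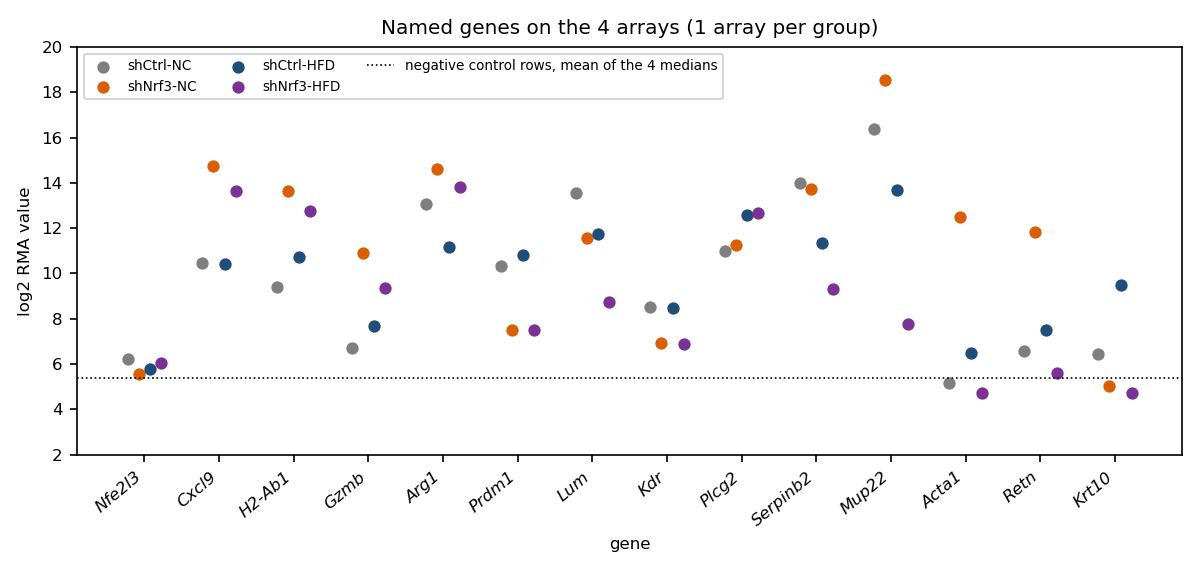
The log2 RMA value of 14 named genes is shown on each of the 4 arrays, 1 point per array, with a dotted line at the level of the negative control rows. Cxcl9 lies at 14.73 and 13.66 on the arrays labelled shNrf3 against 10.47 and 10.43 on those labelled shCtrl, Mup22 is lowest on the shNrf3-HFD array (7.75), and Acta1 stands apart on the shNrf3-NC array alone (12.51).

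Between diets, matrix genes and inflammatory cytokine genes were lower in HFD for both constructs. The matrix list had median HFD minus NC differences of -0.58 with shCtrl and -0.94 with shNrf3 (percentile 0.00 in each), with 13 and 21 of 27 genes lower, and -0.92 with shCtrl after loess (18 lower). Lumican differed by -1.78 and -2.84, decorin (Dcn) by -1.06 and -3.35, Postn by -1.77 and -1.04 and Mmp2 by -0.30 and -2.31. The fibroblast and pericyte list had medians of -0.27 and -0.83 (percentiles 0.18 and 0.00, with -0.48 for shCtrl after loess or over members past the filter only, and a mean of -1.31 for shNrf3), with dermatopontin (Dpt) at 0.07 and -2.82. With shNrf3, skeletal muscle markers (28 of 32 lower, median -1.39, or -2.27 over members past the filter only) and adipocyte markers (12 of 20 lower, median -0.99) were also lower in HFD. The NC array of that comparison is the one high in muscle and fat genes, and whether its matrix values have the same source was not tested. Cytokine and chemokine genes had medians of -0.48 and -0.87 (percentile 0.00 in each), with 11 and 17 of 27 lower, and -0.76 with shCtrl after loess. Among them Il6 differed by -2.20 and -1.53, Ccl2 by -1.77 and -1.39, Ccl8 by -1.52 and -2.65 and the acute phase gene Saa3 by -0.54 and -5.10. T cell markers had medians of -0.58 and -0.90 (percentiles 1.83 and 0.00, with -0.89 for shCtrl after centring), with Cd3g at -0.40 or lower and -2.45 or lower and the checkpoint gene Ctla4 at -1.04 and -1.34, at levels from 5.0 to 7.8 that lie near the negative control rows. B and plasma cell markers had medians of -0.57 and -0.24 (percentiles 1.77 and 3.87, with -0.88 for shCtrl after centring and -0.31 over members past the filter only).

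Mup22, named by its rank, read 16.36 and 18.53 on the NC arrays and 13.68 and 7.75 on the HFD arrays (shCtrl and shNrf3 in each case), and Mup9, Mup19 and Mup2, named in the same way, had the same order of arrays. The major urinary protein genes were not a list fixed beforehand. The plasminogen activator inhibitor gene Serpinb2 (-2.68 and -4.41), the hyaluronan-binding protein gene Tnfaip6 (-2.78 and -2.19), Rgs16 (-2.23 and -2.02), Fam110c (-2.56 and -1.95) and the cytochrome P450 gene Cyp2e1 (-1.84, and -4.72 or lower) were also lower in HFD. Higher in HFD were Stfa2, a cystatin family gene of myeloid cells (1.97 and 2.02), the granzyme gene Gzmg (1.89 and 2.11), Sh2d1b1 (1.70, and 2.53 or more), Rnf152 (0.95 or more and 1.44 or more), Serpinb5 (1.52 and 1.62), the folate carrier Slc19a1 (1.52 and 1.46), the phospholipase Plcg2 (1.62 and 1.42), Epb41l4b (1.70 and 1.42), the fractalkine receptor Cx3cr1 (1.37 and 1.43) and the tricellular junction gene Marveld2 (1.65 and 1.26). Epithelial and renal tubule genes had medians of 0.30 with shCtrl (percentile 74.3) and 0.48 with shNrf3 (percentile 100.0), with Krt18 at 0.74 and 0.76, Cldn4 at 0.84 and 0.99 and Epcam at 0.47 and 1.54. Within the hypoxia and glycolysis list, whose medians were 0.27 and -0.32 (percentiles 36.1 and 0.35), Lox (-1.73 and -1.88), Adm (-1.21 and -1.81) and Vegfa (-1.01 and -1.08) were lower with both constructs.

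Counts between diets were 1468 genes higher and 391 lower for shCtrl (79.0% higher, median difference 0.26). They were 866 and 621 after loess (58.2%), 725 and 849 after centring (46.1%), and 825 and 740 from the comparison's own median. For shNrf3, 187 genes were higher and 504 lower (27.1% higher), 198 and 493 after loess (28.7%) and 282 and 394 after centring (41.7%). Both constructs shared 36 genes higher in HFD (27.4 for independent lists) and 54 lower (19.7), while 77 were higher with shCtrl and lower with shNrf3 (73.8) and 9 the reverse (7.30). After loess the last 2 counts were 53 (42.6) and 16 (12.3). Across genes the 2 diet differences correlated with r of 0.02 and rho of -0.05. The additive limma fit called 0 genes for diet. It had 292 of 10021 genes at an unadjusted p under 0.05, a smaller share than the 0.05 expected with no differences. With loess values the limma fit called 1 gene, Serpinb2 (log2 difference -3.72, adjusted p 0.0229). After centring, the limma fit called 11 genes lower in HFD and 0 higher, Serpinb2, Mup9, Mup19, Mup22 and Mup2 among them, with adjusted p from 0.00165 to 0.0496. Over the 10 limma fits its smallest adjusted p ran from 0.00165 to 0.999. With 1 array left out the shared counts were 63 to 645 higher (highest without shNrf3-NC) and 90 to 190 lower (highest without shCtrl-NC).

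With shNrf3 alone the largest diet differences beside those named above were Ipw (3.88 or more) in the higher direction and Acta1 (-7.12 or lower) in the lower. Vash2 (1.86 or more) ranked among the 5 highest only through a reading below the control median. With shCtrl alone the largest diet differences in the lower direction were those of Mup9 (-3.55), Tnfaip6 (-2.78), Mup22 (-2.69), Serpinb2 (-2.68) and Pramel7 (-2.43 or lower, among them only through such a reading), and in the higher direction those of Krt10 (3.05) and of 4 genes lowest on the shCtrl-NC array. Cops9 (3.62), Mtch1 (3.16), Rpl38 (2.96) and Cip2a (2.95) read lower on that array than on each of the other 3. Ribosomal protein genes had medians of 1.02 for the NC knockdown difference and 1.02 for the diet difference with shCtrl (percentiles 99.9 and 99.9), which share that array. After loess these 2 medians were 0.59 and 0.57. They were -0.06 and -0.01 in the other 2 comparisons of the deposited values (percentiles 77.1 and 67.3). Rps15 differed by 2.60 and 2.45 in the first pair and Rps9 by 2.02 and 1.96. Oxidative phosphorylation genes had medians of 0.71 and 0.72 in the first pair (percentiles 99.9 and 99.7), which were 0.44 and 0.31 after loess, against -0.13 and -0.16 in the others (55.7 and 9.78). Proteasome genes had medians of 0.72 and 0.59 (percentiles 99.7 and 96.9), which were 0.45 and 0.23 after loess, against -0.17 and -0.14 (36.7 and 13.8). Psma7 differed by 1.88 in the NC knockdown comparison and 0.68 in the HFD one.

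**Figure D3:**
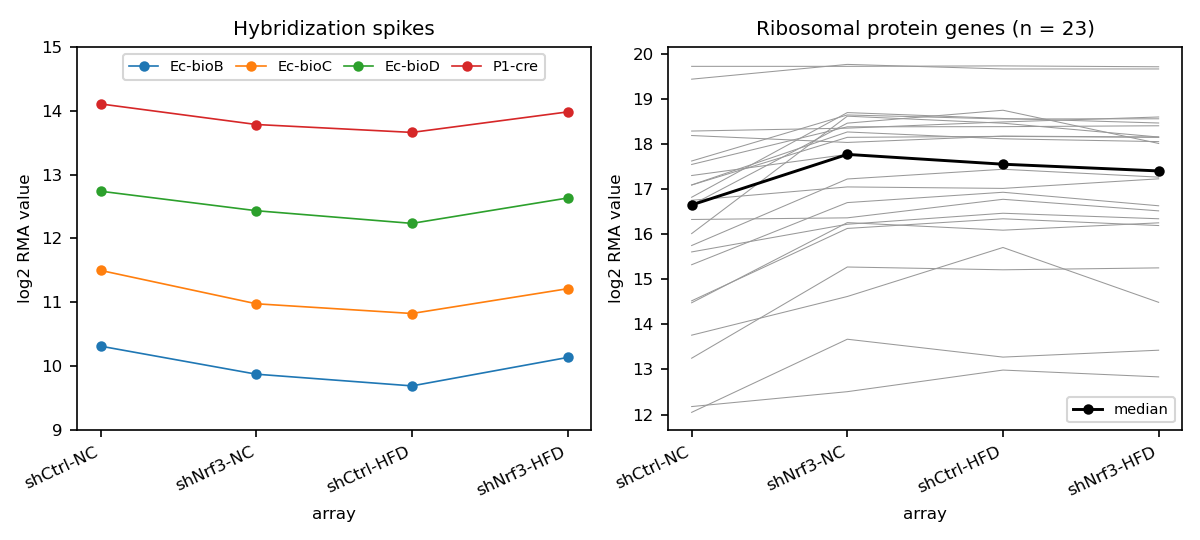
Lines join the log2 RMA values of single probe sets across the 4 arrays, the 4 hybridization spikes on the left and 23 ribosomal protein genes on the right, with their median in black. The spikes read highest on shCtrl-NC (P1-cre at 14.11), where the ribosomal median is lowest (16.65 against 17.40 to 17.77).

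The construct by diet difference, the knockdown difference in HFD minus that in NC, was 1 or more on the log2 scale for 646 genes and -1 or less for 2193 (22.8% higher, median -0.30), against 997 and 1518 after loess (39.6%), 1403 and 1150 after centring (55.0%), and 1133 and 1417 from its own median. With 1 array per group it has no test. It combines the scatter of all 4 arrays, with an SD over genes of 0.94 against 0.78 and 0.60 for knockdown in NC and HFD. Its counts at the same threshold are therefore not to be set against those of single comparisons. With readings below the control median set to it, its lowest values were those of Mup2 (-8.49), Acta1 (-8.21 or lower), Mup22 (-8.09), Mup19 (-7.72) and Retn (-7.15), and its highest those of Ipw (3.91, with 3 such readings), Igfl3 (2.93 or more), Atg16l2 (2.88), Zfp597 (2.84 or more) and Cyp2f2 (2.69). Myl1 (-7.07 or lower), Myh8 (-5.83 or lower) and Pramel7 (2.52 or more) ranked among the 5 only through such readings, and the order of the bounds is not read. Type I interferon response genes had a median knockdown difference of 0.36 in NC (percentile 89.8) and of -0.94 in HFD (0 of 26 higher and 17 lower, percentile 0.00). Between diets they were higher in HFD with shCtrl (20 of 26, median 0.94, percentile 100.0, with 0.61 after loess) and lower with shNrf3 (median -0.52, percentile 0.00). The HFD knockdown and shCtrl diet comparisons share the shCtrl-HFD array, so their medians of -0.94 and 0.94 are not separate findings. The interferon-stimulated genes Ifit1 (1.30 in NC and -1.65 in HFD), Oas1a (0.83 and -1.74) and Irf7 (0.24 and -2.43) and Ifi27l2a (2.51 and -1.76) had the largest construct by diet differences of this list. The interferon-gamma list had diet medians of 0.47 with shCtrl (percentile 84.9) and -0.65 with shNrf3 (0.00), and the macrophage list 0.50 (93.3) and -0.39 (0.09).

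Immediate early genes had knockdown medians of 0.40 in NC and -0.47 in HFD (percentiles 85.1 and 1.60) and diet medians of 0.69 and -0.49 (97.8 and 0.09), with Egr1 at -0.19 and -2.34 for knockdown. After loess the diet median with shCtrl was 0.28, at the 93.0th percentile, and after centring the HFD knockdown median was -0.26. Cell cycle genes had knockdown medians of 0.25 and -0.46 (percentiles 67.6 and 0.32) and diet medians of 0.61 and -0.27 (98.5 and 0.55). For knockdown 10 of 32 were 1.5-fold or more higher and 3 lower in NC, and 0 higher and 13 lower in HFD. Mki67, at -0.69 and -1.23 for knockdown, was among the few lower in NC. After loess the HFD knockdown median was -0.30 and the diet median with shCtrl 0.27, and after centring the diet median with shNrf3 was -0.16. Unfolded protein and heat shock genes had knockdown medians of 0.92 and -0.24 (percentiles 100.0 and 24.9) and diet medians of 0.32 and -0.74 (45.4 and 0.00), with Hspa1b at 2.14 and -0.70 and calreticulin (Calr) at 2.16 and -0.16 for knockdown. NRF2-type antioxidant genes had knockdown medians of 0.63 and 0.06 (percentiles 99.4 and 94.1) and diet medians of 0.23 and -0.39 (42.5 and 0.24). Of the 22 measured NRF2-type genes 11 were 1.5-fold or more higher and 0 lower in NC, and 3 higher and 3 lower in HFD. Nqo1 (1.69 and 1.08) and Hmox1 (1.38 and 1.30) were higher in the tumors labelled shNrf3 in both diets. Both lists lay outside the middle 95% of random lists only in the NC knockdown and shNrf3 diet comparisons. These share the shNrf3-NC array, and skeletal muscle (1.12 and -1.39) and adipocyte markers (1.03 and -0.99) moved with it. The adipocyte list also lay outside that range in the HFD knockdown and shCtrl diet comparisons, which do not use that array.

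Cholesterol synthesis and uptake genes had knockdown medians of 0.33 and -0.18 (percentiles 84.3 and 41.2) and diet medians of 0.67 and 0.01 (98.6 and 63.2, with 0.39 for shCtrl after loess), with squalene epoxidase (Sqle) at 1.95 and -0.23 for knockdown. Fatty acid oxidation genes had knockdown medians of 0.28 and -0.07 and diet medians of 0.31 and 0.05, all within the middle 95% of random lists. Cpt1a, which brings fatty acids into mitochondria, was higher in HFD with both constructs (1.19 and 1.15). ATF4 and amino acid response genes had knockdown medians of 0.04 and -0.31 (percentiles 30.6 and 5.68) and diet medians of 0.56 and -0.11 (98.4 and 20.9, with 0.31 for shCtrl after loess), with the amino acid transporter gene Slc7a5 higher in HFD with both constructs (1.88 and 1.12). Endocytosis and macropinocytosis genes had knockdown medians of 0.06 and -0.17 and diet medians of 0.24 and -0.02, all within the middle 95% of random lists, with Rab34 lower in both arrays labelled shNrf3 (-0.99 and -1.33). The p53 and apoptosis list had knockdown medians of 0.28 and -0.11 (percentiles 80.6 and 52.9) and diet medians of 0.41 and -0.31 (81.8 and 1.85, with -0.21 for shNrf3 after centring, -0.20 over members past the filter only and a mean of -0.19). For hypoxia and glycolysis the knockdown medians were 0.26 and 0.01 (percentiles 59.8 and 92.6), and Car9, a carbonic anhydrase induced by low oxygen, was higher in both arrays labelled shNrf3 (2.75 and 1.14).

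**Figure D4:**
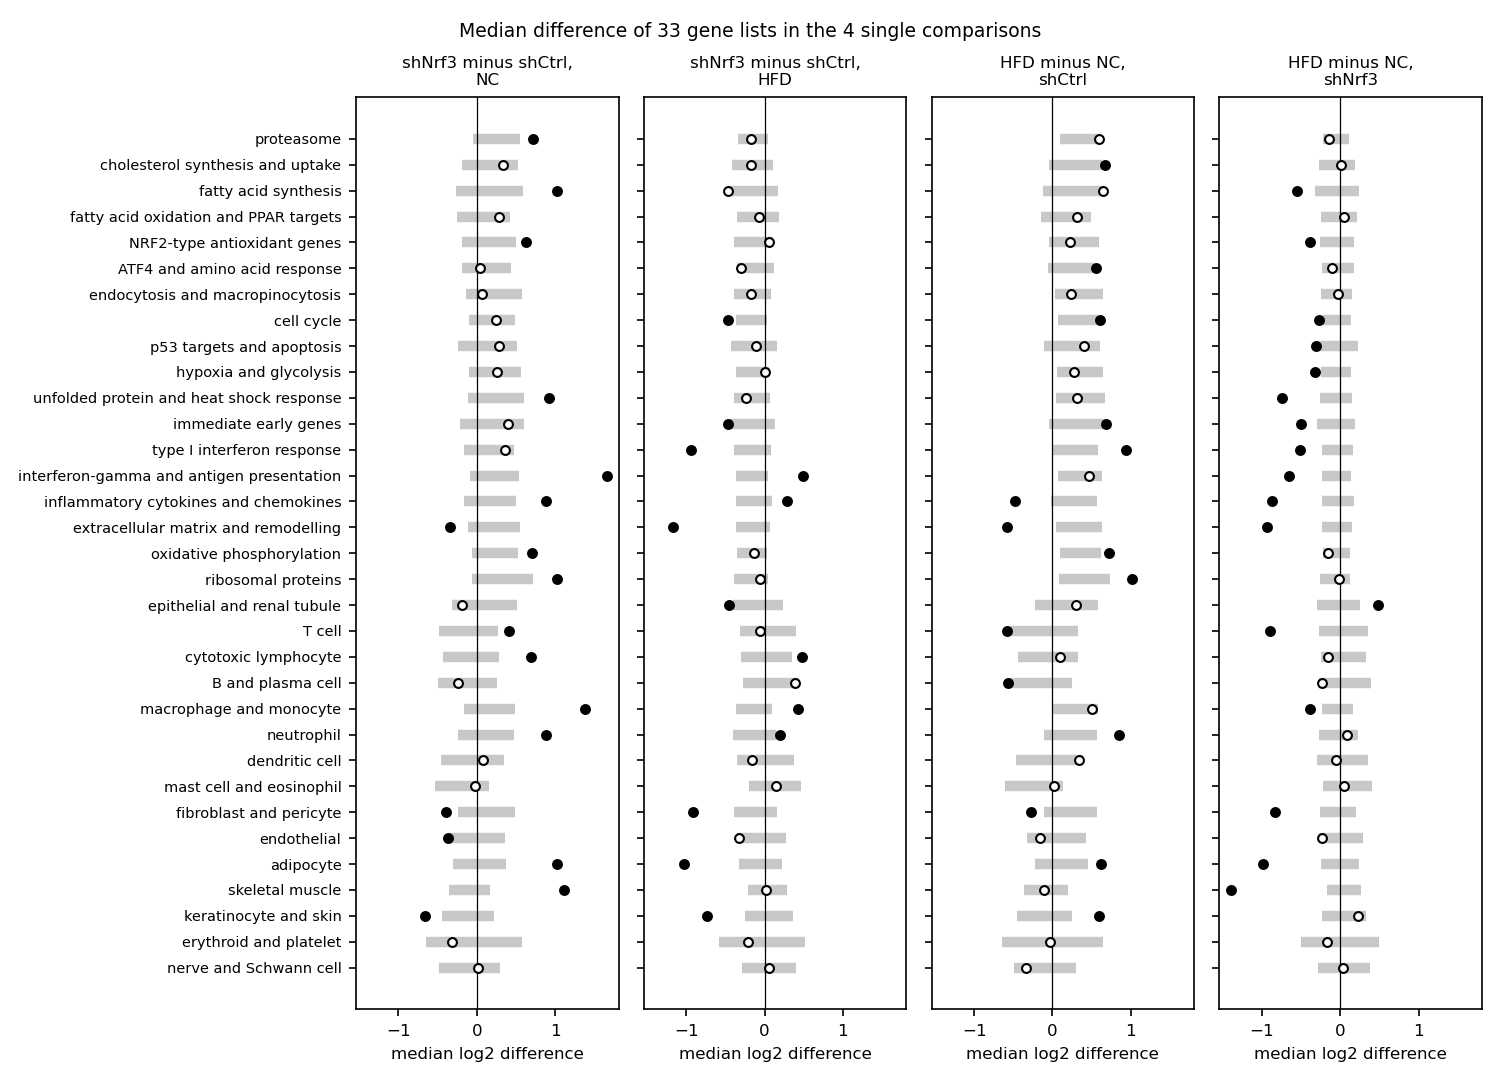
Points are the median log2 difference of each of 33 gene lists in the 4 single comparisons, and grey bars span the middle 95% of 10000 random lists matched on level (filled points lie outside). The interferon-gamma list lies above its bar in both knockdown comparisons (1.66 and 0.49), the matrix list below it in all 4, and the adipocyte list on opposite sides of it (1.03 in NC and -1.02 in HFD).

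The remaining cell type lists stood out less. Dendritic cell markers had knockdown medians of 0.09 and -0.15 and diet medians of 0.33 and -0.05, and mast cell and eosinophil markers had -0.02, 0.15, 0.02 and 0.05 in the same order. Erythroid and platelet markers had -0.32, -0.21, -0.03 and -0.17, and nerve and Schwann cell markers 0.02, 0.05, -0.33 and 0.04. All of these lay within the middle 95% of random lists, as did the knockdown medians of the B and plasma cell list (-0.24 and 0.39). For the lists described only for knockdown above, the diet medians with shCtrl and shNrf3 were 0.09 and -0.16 for cytotoxic lymphocytes (percentiles 76.7 and 8.47), 0.85 and 0.08 for neutrophils (100.0 and 81.4), -0.16 and -0.23 for endothelium (13.3 and 5.61), 0.59 and 0.23 for keratinocytes and skin (100.0 and 89.1), 0.62 and -0.99 for adipocytes (99.7 and 0.00), -0.11 and -1.39 for skeletal muscle (40.04 and 0.00) and 0.64 and -0.55 for fatty acid synthesis (97.0 and 0.03). With shCtrl the neutrophil median was 0.51 after loess, and after centring the keratinocyte and adipocyte medians were 0.28 and 0.31.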

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

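The tests on exchanged labels, on the shCtrl-NC array alone, on macrophages and on the hybridization spikes were chosen after the result was at least partly seen, and the other tests before. None of the differences between groups in this part was tested, since each group has 1 array.

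Nfe2l3 was lower in the array labelled shNrf3 in NC and higher in the one labelled shNrf3 in HFD, and the knockdown differences of the diets lie 0.94 apart on the log2 scale. Exchanged labels of the HFD arrays could make the split that pairs shNrf3-NC with the array labelled shCtrl-HFD the stronger one. It separated 33 genes by 2-fold or more, against 93 for the split by construct labels and 45 for that by diet (24, 90 and 52 after loess). The SDs over genes of these splits were 0.47, 0.52 and 0.48. With 1 array per group, differences between single tumors can also make a split the stronger, so the counts do not decide on exchanged labels. Scatter of probe sets at this level remains a candidate explanation, since the HFD difference lies at the 66.4th percentile of the 1000 genes nearest in level. Stromal and immune cells without the hairpin, and weaker knockdown in the HFD tumor, stay open and were not tested.

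Expressed genes read lower in the median on the shCtrl-NC array (8.61) than on the other 3 (8.72 to 8.93), ribosomal protein genes among them, and 41.6% of the filtered genes were lowest there. The 4 hybridization spikes, which are added to every sample alike, read higher there than on each other array, by at least 0.11 on the log2 scale, so weaker signal from the sample's RNA is a candidate explanation. After cyclic loess the ribosomal list stayed at the 99.4th percentile in the NC knockdown comparison, with its median down from 1.02 to 0.59. This does not decide on a shift that depends on level alone. The loess span was 0.7 of the rows, too wide to follow a shift confined to the highest levels, where these genes lie. Degraded RNA in that sample and a biological difference of the shCtrl-NC tumor stay open and were not tested.

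Interferon-gamma and antigen presentation genes were higher in both arrays labelled shNrf3. The shCtrl-NC array cannot make the HFD part of this pattern, which does not use it (median 0.49, percentile 100.0). That HFD median is itself part of the pattern and was seen beforehand, so it is no separate test. In HFD 5 of the 33 lists lay above the random range and 8 below it. The NC part does use the shCtrl-NC array. For the list as a whole a larger share of macrophages is a candidate explanation, since its median lay within 1.5-fold of that of the macrophage and monocyte list, which was fixed beforehand and shares no gene with it (0.27 above it in NC and 0.06 in HFD). This holds for medians only. The mean of the interferon-gamma list lay above its median, at 2.06 against 1.66 in NC and 0.73 against 0.49 in HFD. The median of 7 MHC class II genes exceeded that of 10 macrophage genes by 2.01 in NC and 1.11 in HFD, but both sets were picked after their values were seen, so this decides nothing. An effect of the construct on these genes, other class II-bearing cells and a difference between single tumors stay open.

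Other lists lay outside the range of random lists on opposite sides in 2 groups. For the adipocyte list the knockdown median in HFD minus that in NC was -2.05, and the diet median with shNrf3 minus that with shCtrl was -1.61. For each gene these are 1 and the same construct by diet difference, whose median over the list was -1.72. The diet medians with shNrf3 minus those with shCtrl differed by -1.46 for the type I interferon response, -1.19 for immediate early genes and -0.88 for the cell cycle.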

How the results depend on the processing

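Values of 323 genes, those named by rank and the list members the naming rule can take, were run under loess, centring and the mean of probe sets. Of these 3875 stayed within 0.47 of their main values and 1 moved (Cd83 for knockdown in NC, from 1.11 to 0.42 with the mean of probe sets). Centring shifts every gene of a comparison by the same amount, under 0.47, so its 1292 values could not move. The mean of probe sets can change only the 55 genes with several. The 1292 values under loess were therefore the only ones all free to move. With readings below the negative control median of their array set to it, a choice made after seeing the data, 1087 stayed and 51 moved, and comparisons with both readings below it have no value. The counts of each comparison and those shared the same way stayed within 1.5 times, while 1 of the counts in opposite ways moved. Of the list medians under 5 alternatives 608 stayed within tolerance and 52 moved. With loess 12 moved, the ribosomal median for knockdown in NC and 11 for diet with shCtrl (ribosomal, oxidative phosphorylation, proteasome, cell cycle, immediate early, type I interferon, interferon-gamma, unfolded protein, hypoxia, matrix and neutrophil lists). With centring 17 moved, 4 for knockdown in HFD (cell cycle, interferon-gamma, oxidative phosphorylation and proteasome) and 13 for diet with shCtrl (these 4 and the ATF4, endocytosis, hypoxia, unfolded protein, type I interferon, cytokine, matrix, macrophage and skeletal muscle lists). With list means 9 moved (cytotoxic lymphocyte and skeletal muscle for knockdown in NC, interferon-gamma for knockdown in both diets, and adipocyte, fibroblast, cytokine, unfolded protein and skeletal muscle for diet with shNrf3). With members past the filter only 14 moved (cytotoxic lymphocyte, skeletal muscle, mast cell and nerve for knockdown in NC, fibroblast, B cell and skeletal muscle for knockdown in HFD, cytotoxic lymphocyte and nerve for diet with shCtrl, and adipocyte, skeletal muscle, fatty acid oxidation, keratinocyte and mast cell for diet with shNrf3). Of those outside the random range 0 changed sign under loess or centring. Of the 69 inside that range 17 changed sign under loess and 23 under centring, so their directions are not read. The additive fit stayed at 0 calls with trend, robust, no filter, the filter at the 75th percentile, the filter on the highest array and the mean of probe sets, the last 2 of which were added after seeing the data, as was the fit after centring. Without any 1 array it has 0 residual degrees of freedom. Signal near the negative control rows limits what low genes such as Nfe2l3 can show. Counts below are given as higher and lower.

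With no filter (more genes near background), 1303 genes were lower for knockdown in NC, 1009 higher for knockdown in HFD, 1537 lower for diet with shCtrl, 738 and 805 for diet with shNrf3, 2698 higher for construct by diet, and 63 and 90 shared between diet comparisons. Correlations were -0.0277 for knockdown and -0.0448 for diet. At the 75th percentile filter (fewer genes) the counts were 836 and 175 and 95 and 336 for knockdown in NC and HFD, 859 and 109 and 46 and 244 for diet with shCtrl and shNrf3, 174 and 1257 for construct by diet, 54 and 42 shared for knockdown and 11 and 30 for diet, with correlations of 0.1907 and 0.0751. With the filter on the highest array, 630 were lower for diet with shCtrl, 298 higher for diet with shNrf3 and 984 higher for construct by diet. With a 1.5-fold threshold the counts were 2690 and 1352, 914 and 2082, 3127 and 1076, 886 and 1442 and 1382 and 3723 in the same order of comparisons, with 307 and 372 shared for knockdown and 276 and 212 for diet.

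With cyclic loess, 866 and 621 were counted for diet with shCtrl and 997 higher for construct by diet, and the additive fit called 5 and 4 for knockdown and 1 lower for diet. With centring, 790 were lower for knockdown in NC, 481 and 383 for knockdown in HFD, 725 and 849 for diet with shCtrl, 282 higher for diet with shNrf3 and 1403 and 1150 for construct by diet, and the additive fit called 17 and 10 for knockdown and 11 lower for diet. The cause was not tested for either scaling. Leaving out 1 array, chosen after seeing the data, gave shared counts of 101 to 697 higher and 119 to 240 lower for knockdown and 63 to 645 and 90 to 190 for diet, larger by construction since 2 comparisons then share an array.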

Other observations

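Between the arrays labelled shNrf3 and shCtrl, the proteasome subunit gene Psmb9 differed by 4.14 in NC and 0.15 in HFD, Psmb10 by 2.41 and 0.15 and Psmb8 by 1.61 and 0.49, and the chemokine gene Cxcl11 by 2.46 and 0.08. All of these are members of the interferon-gamma and antigen presentation list. Jchain, the joining chain of secreted antibodies, differed by 1.37 in NC and 0.52 or more in HFD for knockdown and by -0.19 or lower with shCtrl and -1.04 with shNrf3 for diet, at levels from 4.54 to 6.92 near the negative control rows. The haemoglobin scavenger receptor gene Cd163 was lower in HFD with both constructs (-1.24 and -1.08).

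The granzyme genes Gzmc (2.81 with shCtrl and 1.03 with shNrf3) and Gzmf (2.03 and 1.24), which belong to a cluster of similar copies, were higher in HFD with both constructs. Genes in this part were picked after their values were seen, and every direction in either diet rests on labels that Nfe2l3 does not bear out.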
